A study of Mus musculus with 12 samples.

How the data were processed

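Whole-brain RNA of 12 mouse samples of 4 genotypes, 3 per genotype, was measured on 1-colour Affymetrix 3' expression arrays. Per the labels' protocols, RNA was isolated with a spin-column kit and total RNA was amplified and labelled with biotin in a one-cycle protocol. The deposited values are log2 signals per probe set as the authors processed them, and the R package affy is named for this, per the submitters' processing notes. Its version, the background correction, the normalization and the summary of probes are not given in the sources used here. The base 2 of the log was inferred from the values, which ran from 2.36 to 13.81 with medians per array of 6.98 to 7.07. No scanner files were used here, so signals could not be set against background and a low level has no detection call.

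Of 22690 probe sets in the table, 64 were control probe sets. In the platform annotation, which can be old, 20380 probe sets had 1 gene and 691 had several, and 1555 were not listed and are unnamed here, not without a gene. Entrez identifiers of 20351 probe sets matched the reference table, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 12393 genes, 4956 of them with several probe sets. Probe sets with several genes or no name were left out of the gene tests. All array columns of the table belonged to samples of this series.

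Samples were grouped by the genotype in their labels. The labels do not give sex, batch or scan date. Genes were tested with limma (lmFit, contrasts.fit and eBayes, version 3.58.1 in R 4.3.3) in 1 fit of all 12 arrays with genotype as the only term, 8 residual degrees of freedom and a prior of 4.67 degrees of freedom. The 6 comparisons were USP18ko, IFNARko and the double knockout each against WT, the double knockout against each single knockout, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. An exact test of 3 against 3 arrays cannot give a two-sided p under 0.1, so calls rest on the spread that limma shares across genes.

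Gene lists were tested with limma's camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry's directional test. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move, on balance, in 1 direction. There were 31 lists of pathways and of cell type markers, of which 27 with at least 5 measured members were tested, and 76 list members had no value. In 20 of the 162 list tests the median, the mean and the direction of the test differed in sign, and 0 of these 20 were called. The groups, comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

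The genes named for a comparison are Usp18 and Ifnar1, then, among called genes whose groups do not overlap, the 15 with the largest positive and the 8 with the largest negative log2 fold change, and then up to 4 called members with the smallest p of each list. For the interaction, overlap was not considered. Where fewer than 5 genes were called, the 5 with the smallest p are named as well. Values of such genes in other groups are also given. Exceptions are the sex-linked and control transcripts of the array checks, the neighbours of both knocked-out genes and genes said to be named after their values were seen.

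The gene test was tested on simulated data with 12393 genes, of which 200 changed, in 10 runs. For USP18ko against WT it recovered 37.8%, 85.2% and 98.9% of genes with simulated log2 changes of 0.5, 1 and 2, with 4.65% false among the called, and for the interaction 8.96%, 62.2% and 96.1%, with 4.64% false. In simulated data for USP18ko against WT, camera called a list shifted by 0.5 in 10 of 10 runs and 0 of 260 unshifted lists. The simulated genes were independent of each other, each with the same spread in all arrays. These runs therefore do not show how many false calls arise where genes are correlated or an array stands apart.

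Alternatives were the average of a gene's probe sets, each probe set by itself, only genes above the 40th percentile of mean signal, quantile normalization or median centring on top of the deposited values, array weights, a trended and robust variance, an absolute log2 fold change of at least 1, the replicate number as a block, only the 2 groups compared, other neighbourhood widths and each array left out in turn. Chosen after seeing the data were a covariate for the Y-linked gene Eif2s3y, gene-by-gene array weights, and fits without 2 arrays at a time.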

Results

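Transcript levels were measured in whole-brain lysates of adult, untreated mice kept under specific-pathogen-free conditions, with 1 Affymetrix 3' expression array per sample. The 12 arrays fell into 4 genotypes of 3 arrays each: wild type (WT), a knockout of Usp18 (USP18ko), a knockout of Ifnar1 (IFNARko) and the double knockout (USP18ko:IFNARko). Usp18 encodes a protease that removes the ubiquitin-like protein ISG15 from its targets and that restrains signalling through the type I interferon receptor. Ifnar1 encodes 1 of the chains of that receptor. The question was what Usp18 does in the mouse central nervous system, and the double knockout shows which differences of the single knockout were also seen without the receptor. Levels of 12393 genes were compared as log2 signals with limma. The labels do not say whether the 3 replicates of a genotype were separate animals, so p-values measure only the spread between these samples, which may be technical. In WT and the double knockout sex-linked transcripts differed between replicates, so the 3 arrays of each of these groups did not all hold the same RNA. With 3 arrays per group, the number of arrays limits the precision of every value given here.

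The targeted genes were examined first. The Ifnar1 probe set read 7.44 to 8.21 in the WT arrays and 7.76 to 8.01 in the USP18ko arrays, against 6.24 to 6.59 in the IFNARko arrays and 6.56 to 6.68 in the double knockout arrays, so its groups with and without the Ifnar1 knockout did not overlap. The Usp18 probe set read 4.36, 4.36 and 4.04 in the WT arrays and between 3.50 and 3.76 in the other 9 arrays, the IFNARko arrays included. Mean Usp18 signals were 4.26 ± 0.19 in WT, 3.63 ± 0.12 in USP18ko, 3.58 ± 0.08 in IFNARko and 3.64 ± 0.11 in the double knockout (SD, n = 3 each). These levels lie near the bottom of the arrays' range of 2.36 to 13.81, and no detection calls were used here. Each gene had 1 probe set, whose place relative to the deleted part is not given in the sources used here, and a probe set outside the deleted part checks nothing.

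Signs of RNA quality and sex-linked transcripts were then examined in each array. IFNARko replicate 1 had a beta-actin 3' minus 5' log2 difference of 1.48, a sign of RNA or labelling quality, against 0.20 to 0.54 in the other 11 arrays, and its correlations with the other arrays were 0.963 to 0.974, against 0.983 to 0.998 among the rest. Xist, transcribed from the inactive X chromosome, read 10.17 in WT replicate 1 and 11.21, 10.34 and 11.34 in double knockout replicates 1, 2 and 3, against 4.98 to 5.69 in the other 8 arrays. Eif2s3y, on the Y chromosome, read 3.18 in WT replicate 1 and 3.05 and 3.22 in double knockout replicates 1 and 3, and 7.16 to 8.94 in the other 9 arrays. Double knockout replicate 2 thus carried both signals, with an Eif2s3y level of 7.16 beside its high Xist. The USP18ko and IFNARko arrays all had the Y-linked signal and low Xist, so these markers differed between the double knockout and both single knockouts. By themselves, both comparisons of the double knockout with a single knockout cannot tell an effect of genotype from one of sex. The same groups enter the interaction.

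**Figure D1:**
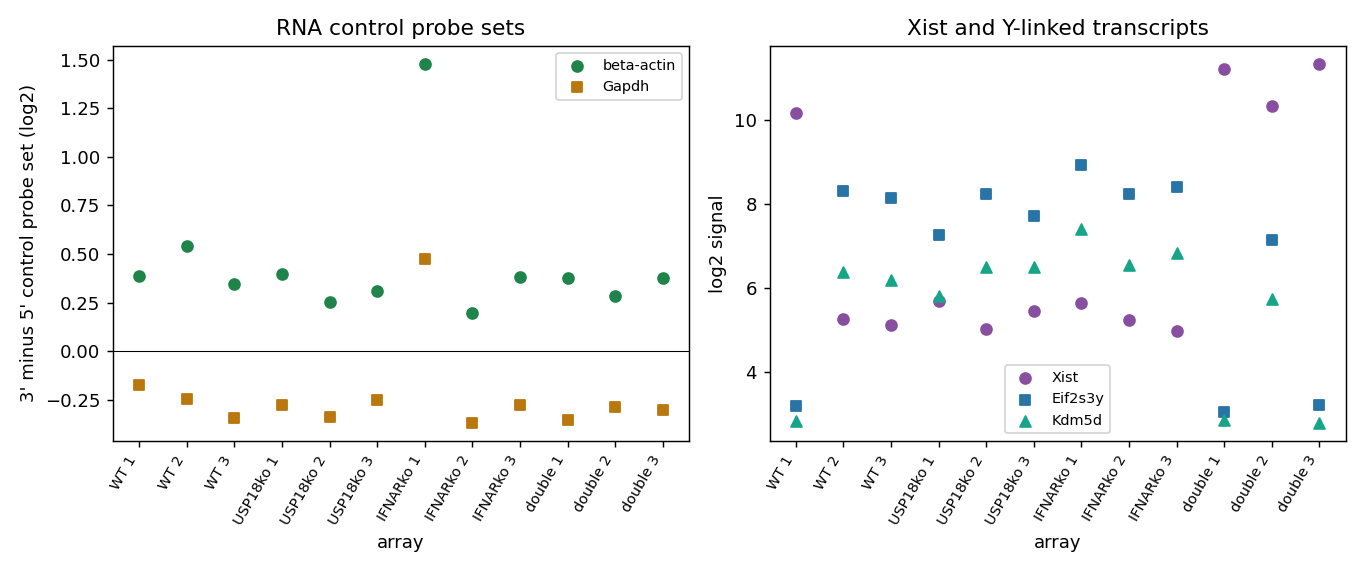
The left panel plots, for each of the 12 arrays, the log2 signal of the 3' minus the 5' control probe set of beta-actin (circles) and Gapdh (squares), and the right panel plots the log2 signals of Xist, Eif2s3y and Kdm5d. IFNARko replicate 1 stands at 1.48 for beta-actin, the 3 double knockout arrays and WT replicate 1 have Xist above 10, and double knockout replicate 2 also has Eif2s3y at 7.16.

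USP18ko was compared with WT to see what loss of Usp18 does while the receptor gene is intact. Genes induced by type I interferon were higher in USP18ko brain. Ifit1, which encodes an antiviral RNA-binding protein, rose from a log2 signal of 3.71 ± 0.19 in WT to 8.57 ± 0.24 in USP18ko (SD, n = 3 each), a difference of 4.87 (SE 0.20, adjusted p = 1.40e-08). Ifit3 rose by 4.19 (SE 0.13, adjusted p = 1.63e-09), and Irf7, a transcription factor of the interferon response, by 3.40 (SE 0.12, adjusted p = 4.71e-09). The antiviral genes Rsad2 and Oasl2 rose by 4.06 and 3.65, Ifi27l2a by 4.37, Rtp4 by 3.54, Lgals3bp by 3.44 and Ifi202b by 3.73. Of the 38 measured interferon-stimulated genes, 30 rose and 1, Usp18 itself, fell, or 35 and 1 when adjusted over the list alone, and the list's median log2 fold change was 2.08 (adjusted p = 2.41e-04 with an estimated correlation). Among 14 interferon signalling components, Irf9 rose by 0.88 (SE 0.12, adjusted p = 0.0010), and 2 rose when adjusted over the list alone (list median 0.13, adjusted p = 0.00355 with an estimated correlation). Ifih1, a sensor of double-stranded RNA and 1 of 4 measured Aicardi-Goutières syndrome genes, rose by 2.41 (SE 0.19, adjusted p = 5.84e-06). In the ISG15 conjugation pathway, with 4 measured members, the ubiquitin and ISG15 ligase gene Trim25 rose by 1.39 (SE 0.18, adjusted p = 6.57e-04) and the conjugating enzyme gene Ube2l6 by 0.82 (SE 0.16, adjusted p = 0.0220). The Ube2l6 call was lost without WT replicate 1 (0.77), WT replicate 3 (0.82), USP18ko replicate 1 (0.64) or USP18ko replicate 3 (0.85), and with array weights (0.85), these 2 groups alone (0.82) or without both IFNARko replicate 1 and WT replicate 1 (0.77).

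In all, limma called 143 of the 12393 genes at a 5% false discovery rate, 142 higher and 1 lower, and 113 of them differed by at least 1 on the log2 scale. Each of the 142 was higher in all 3 USP18ko arrays than in all 3 WT arrays. At an unadjusted p under 0.05 there were 570 genes, and the 2 groups did not overlap for 1233 genes (9.95%), where chance gives 10%. Chance gives 5% of the 12393 genes at that unadjusted p, which is more than these 570. The same holds for the counts at that p given below, except in IFNARko against WT and in the double knockout against IFNARko. The gene that fell was Usp18, by 0.63 (SE 0.12, adjusted p = 0.0137), a call that was lost without WT replicate 1 (-0.57), WT replicate 2 (-0.57), USP18ko replicate 2 (-0.60) or USP18ko replicate 3 (-0.59), and with array weights (-0.66) or these 2 groups alone (-0.63). Ifnar1 differed by 0.08 (SE 0.17, adjusted p = 1.00). With genes of low mean signal left out 28 genes were called, 108 of the 143 being among those left out, and with array weights estimated gene by gene 345 were called.

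**Figure D2:**
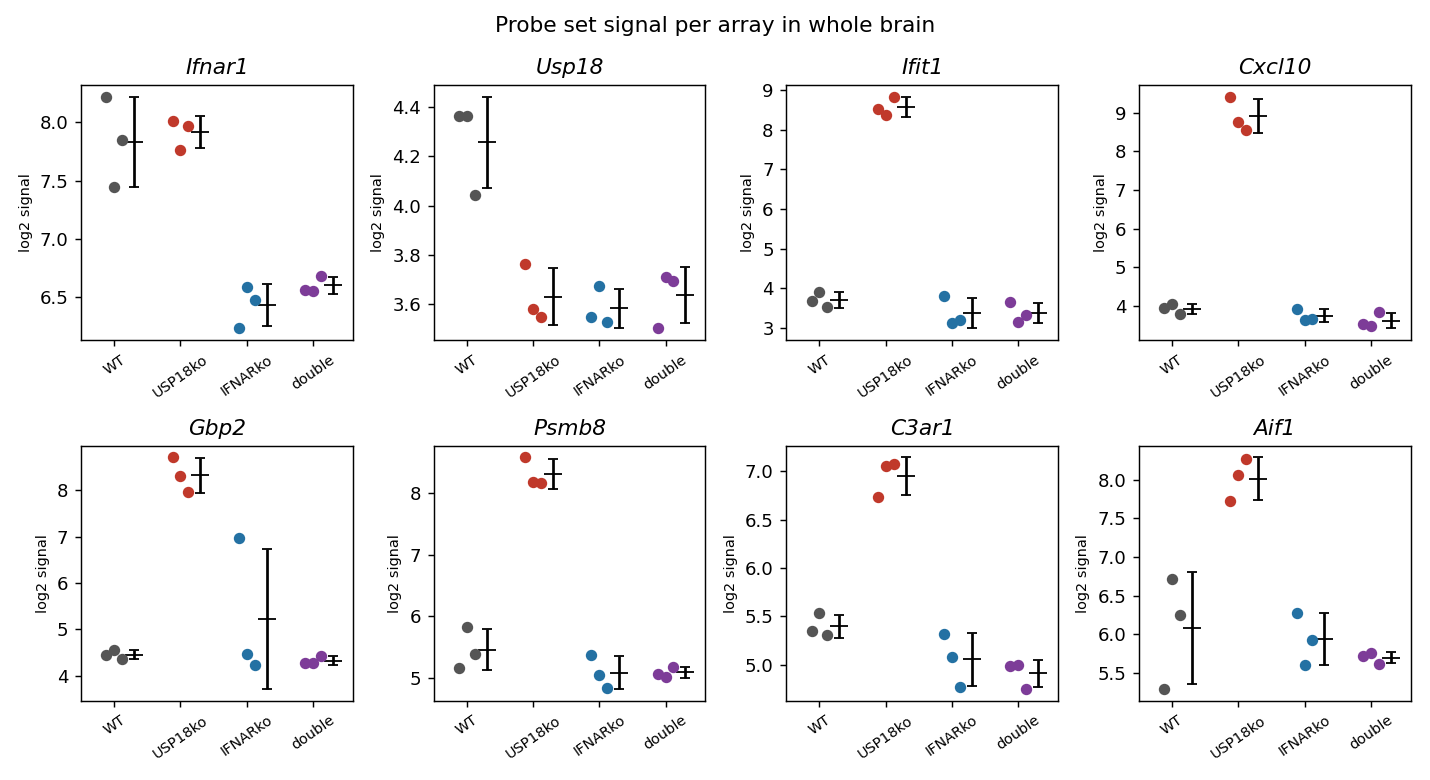
Each panel plots the log2 probe set signal of 1 gene in the 12 arrays (points) with the mean and SD of each group of 3 arrays beside them (bar). Ifit1 and Cxcl10 stand at 8.57 ± 0.24 and 8.92 ± 0.45 in USP18ko and between 3.38 and 3.92 on average in the other 3 groups, and Gbp2 has an SD of 1.51 in IFNARko.

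Chemokines and a list of genes called interferon-gamma-preferring were also higher in USP18ko. The name of that list does not show which interferon raised its members here. Cxcl10, which attracts activated T cells, rose by 5.0 (SE 0.19, adjusted p = 8.13e-09) from 3.92 ± 0.13 to 8.92 ± 0.45 (SD, n = 3 each). The WT signals of Cxcl10 and Ifit1 are not shown to be above background, so these differences are not given as folds. The monocyte and T cell attractants Ccl12, Ccl5 and Ccl2 rose by 4.04, 2.64 and 1.37. Of 25 measured chemokines and cytokines 5 rose, or 9 when adjusted over the list alone (median 0.35, adjusted p = 0.00564 with an estimated correlation). The immunity-related GTPase genes Iigp1, Igtp and Irgm1 rose by 4.64, 3.52 and 2.76, and the guanylate-binding protein genes Gbp2, Gbp6, Gbp2b and Gbp7 by 3.87, 3.50, 3.50 and 2.23. Of 14 interferon-gamma-preferring genes 9 rose, or 11 when adjusted over the list alone (median 2.42, adjusted p = 0.00564 with an estimated correlation). The GTPase families have near-identical members, and the probe set of Gbp2 is of a kind that can bind related transcripts. Those of H2-K1, H2-Aa and Laptm5, named below, are of the same kind.

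Class I and antigen processing genes and complement genes were higher as well. Psmb8 and Psmb9, subunits of the immunoproteasome, rose by 2.85 (SE 0.18, adjusted p = 8.59e-07) and 2.81 (SE 0.18, adjusted p = 1.10e-06), the class I gene H2-K1 by 1.85 (SE 0.17, adjusted p = 2.39e-05), and the peptide transporter gene Tap2 by 1.08. Of 14 class I and antigen processing genes 9 rose, or 13 when adjusted over the list alone (median 1.02, adjusted p = 3.96e-04 with an estimated correlation). Of 7 class II genes 1 rose, H2-Aa, by 1.73 (SE 0.33, adjusted p = 0.0156), or 4 when adjusted over the list alone, and the list's call (median 0.58) was lost with adjusted p = 0.117 with an estimated correlation. The H2-Aa call was itself lost without WT replicate 1 (1.70), WT replicate 3 (1.69), USP18ko replicate 1 (1.78) or USP18ko replicate 3 (1.39). The complement genes C2 and Cfb rose by 1.72 and 1.37, the C3a receptor gene C3ar1 by 1.55 (SE 0.15, adjusted p = 3.78e-05) and Itgb2, the beta chain of complement receptor 3, by 1.14. Of 12 complement genes 7 rose, or 10 when adjusted over the list alone (median 1.26, adjusted p = 0.00303 with an estimated correlation).

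Genes of activated microglia were higher in USP18ko too, and single markers of microglia and perivascular macrophages rose. Aif1, a microglia and macrophage marker, rose from 6.08 ± 0.72 to 8.01 ± 0.27 (SD, n = 3 each), a difference of 1.93 (SE 0.29, adjusted p = 0.00205). Laptm5 rose by 1.25 and Itgam, the alpha chain of complement receptor 3, by 0.80. The call of Laptm5 was lost with these 2 groups alone (1.25), and that of Itgam with these 2 groups alone (0.80), with array weights (0.77) or without WT replicate 3 (0.77). Among genes of activated microglia, Cd52 rose by 3.12 (SE 0.22, adjusted p = 2.02e-06), Lyz2 by 1.71, the pattern receptor gene Tlr2 by 1.31 and the NADPH oxidase gene Cybb by 1.10. Of 18 such genes 5 rose, or 10 when adjusted over the list alone (median 0.45, adjusted p = 6.90e-04 with an estimated correlation). Of 13 microglia markers 3 rose, or 6 when adjusted over the list alone, and the list's call (median 0.41) was lost with adjusted p = 0.0937 with an estimated correlation. The log2 fold changes of the homeostatic microglia markers P2ry12, Tmem119 and Cx3cr1, named after their values were seen, were -0.35, 0.41 and 0.35 and did not pass. Of 9 perivascular macrophage markers 1 rose, Ms4a7, by 1.74 (SE 0.15, adjusted p = 1.11e-05), or 3 when adjusted over the list alone (median 0.30, adjusted p = 0.0636 with an estimated correlation).

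Markers of blood-borne cells included single genes that rose. The leukocyte gene Ptprc, 1 of 15 lymphocyte markers and also expressed by microglia, rose by 2.12 (SE 0.24, adjusted p = 2.23e-04), and the list did not pass (median 0.03, adjusted p = 0.130, and adjusted p = 0.591 with an estimated correlation). Plac8 rose by 3.35 (SE 0.32, adjusted p = 3.78e-05) among 10 monocyte and neutrophil markers, of which 4 rose when adjusted over the list alone (median 0.12, adjusted p = 0.202 with an estimated correlation). Of 23 reactive astrocyte genes 4 rose, or 7 when adjusted over the list alone (median 0.36, adjusted p = 5.24e-04 with an estimated correlation). These 4 were Cxcl10, Gbp2, Psmb8 and Serping1, the C1 inhibitor gene (0.96, SE 0.13, adjusted p = 6.74e-04), all of which are also interferon responsive, while Gfap, an astrocyte filament gene named after its value was seen, differed by 0.70 (adjusted p = 0.831).

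No member of the lists for the main brain cell types passed. This held for 14 astrocyte markers (list adjusted p = 0.552), 12 oligodendrocyte and myelin genes (0.400), 7 oligodendrocyte precursor markers (0.160), 19 neuron and synapse genes (0.715) and 12 endothelial markers. The endothelial list itself was called higher (median 0.05, adjusted p = 0.0248), a call that was lost with adjusted p = 0.202 with an estimated correlation. For the neuron list the median was -0.03 and the mean 0.01, which differ in sign. In all, 13 of 27 lists were called higher by camera with its preset correlation, 8 with an estimated correlation and 9 by fry.

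**Figure D3:**
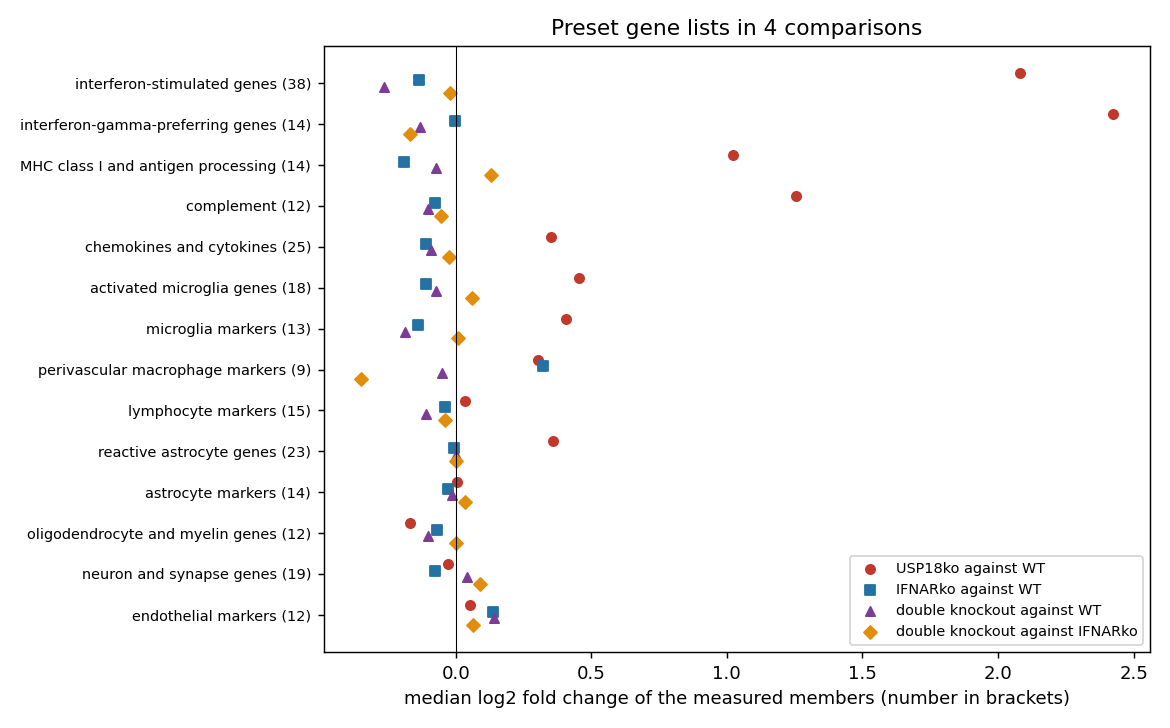
The horizontal axis gives the median log2 fold change over the measured members of 14 gene lists, with the number of members in brackets, in 4 comparisons (marker shapes). The interferon-stimulated, interferon-gamma-preferring, complement and class I lists lie at 2.08, 2.42, 1.26 and 1.02 in USP18ko against WT, while the medians of all 14 lists lie within 0.40 of 0 in the other 3 comparisons.

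IFNARko was compared with WT for the loss of the receptor gene alone. Ifnar1 fell by 1.40 (SE 0.17, adjusted p = 0.0199), and its 3 IFNARko arrays all lay below the 3 WT arrays. It was the only 1 of the 12393 genes called by limma, with 1213 genes at an unadjusted p under 0.05 and 1441 genes without overlap of the groups (11.6%, where chance gives 10%). The next smallest p-values belonged to Clec3b (-1.39, adjusted p = 0.0692), the lipase gene Pnpla3 (-1.28, adjusted p = 0.113), Kcnj9, a potassium channel gene (-1.96, adjusted p = 0.136), and the matrix protein gene Matn4 (-0.96, adjusted p = 0.136), none of which passed. Usp18 differed by -0.68 (SE 0.12, adjusted p = 0.136) and did not pass. The interferon-stimulated genes were called lower as a list (median -0.13, adjusted p = 4.13e-04) and the meningeal fibroblast and perivascular macrophage markers higher (medians 0.30 and 0.32, adjusted p = 4.13e-04 and 0.0335), with no member past the threshold in any of these lists. All 3 calls were lost with adjusted p = 0.478, 0.391 and 0.478 with an estimated correlation, and fry called 0 lists. With gene-by-gene array weights 1264 genes were called, and 11 without IFNARko replicate 1 and WT replicate 1. In a separate fit of 2246 probe sets with several genes or no name, 3 passed, 2 higher and 1 lower. The Ifnar1 call was lost without IFNARko replicate 2 (-1.48), IFNARko replicate 3 (-1.42), WT replicate 3 (-1.40), USP18ko replicate 1 or 3 (-1.40 each) or double knockout replicate 1 (-1.40), with these 2 groups alone (-1.40) and without both IFNARko replicate 1 and double knockout replicate 2 (-1.30). The gene count was 5 without WT replicate 1 or 2, 4 without USP18ko replicate 2, 3 without IFNARko replicate 1 or double knockout replicate 2, 2 without double knockout replicate 3 and 0 without any of the other 6 arrays. The list count was 11 without IFNARko replicate 1, 7 without WT replicate 1, 6 without WT replicate 2 and 1 without IFNARko replicate 2.

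Loss of both genes was compared with WT. Ifnar1 fell by 1.23 (SE 0.17, adjusted p = 0.0394) as did Pnpla3, which encodes a lipase (-1.49, SE 0.20, adjusted p = 0.0394), each with the 3 double knockout arrays below the 3 WT arrays. Limma called these 2 genes, with 507 at an unadjusted p under 0.05 and 1782 without overlap of the groups (14.4%, where chance gives 10%). Tmem87a (-1.98, adjusted p = 0.0880), Epdr1 (-0.61, adjusted p = 0.234), Alox8 (0.68, adjusted p = 0.234) and Usp18 (-0.62, SE 0.12, adjusted p = 0.304) did not pass. The 142 genes higher in USP18ko had a median log2 fold change of -0.18 here (range -0.98 to 0.71), with none past the threshold in either direction, though the same WT arrays enter both comparisons. As a list, the interferon-stimulated genes were called lower (median -0.27, adjusted p = 4.62e-08), and the endothelial (0.14, adjusted p = 0.00510), meningeal fibroblast (0.11, adjusted p = 0.0111) and choroid plexus and ependymal markers (0.17, adjusted p = 0.0111) higher. These 4 calls were lost with adjusted p = 0.434, 0.434, 0.434 and 0.585 with an estimated correlation, and fry called 0 lists. With gene-by-gene array weights 843 genes were called, and 58 without IFNARko replicate 1 and WT replicate 1. The Ifnar1 call was lost without each array but WT replicate 2 and IFNARko replicate 1 (range over all 12 -1.43 to -1.04), and that of Pnpla3 without each array but IFNARko replicates 1 and 2 (range -1.54 to -1.43). Testing each probe set by itself and quantile normalization ended both calls (Ifnar1 at -1.23 and -1.24, Pnpla3 at -1.49 and -1.48). The Ifnar1 call was also lost with dim genes left out or these 2 groups alone (-1.23 each) and without both IFNARko replicate 1 and double knockout replicate 2 (-1.21), and the Pnpla3 call with the Eif2s3y level as a covariate (-1.43). The gene count was 1 without WT replicate 1, USP18ko replicate 2 or IFNARko replicate 2, and 0 without WT replicate 3, USP18ko replicate 1 or 3, IFNARko replicate 3 or any of the 3 double knockout replicates.

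The double knockout was then compared with USP18ko, for the removal of the receptor gene where Usp18 is lost. These groups also differed in sex-linked transcripts, which this comparison cannot set apart. The IFNARko arrays, with Y-linked signal and low Xist like USP18ko, differ from the double knockout in the same way. Over the 142 genes higher in USP18ko, the double knockout differed by a median of -1.67 from USP18ko (range -5.30 to -0.40). From IFNARko it differed by -0.08 (range -0.90 to 0.70). For these genes as a set, this argues against a difference of sex alone as the cause. Interferon-stimulated genes were lower in the double knockout. Ifit1 fell by 5.20 (SE 0.20, adjusted p = 6.22e-09) to 3.38 ± 0.26 (SD, n = 3), and Ifit3 (-4.54, adjusted p = 5.98e-10), Irf7 (-3.76, adjusted p = 1.33e-09), Rsad2 (-4.62), Rtp4 (-4.52), Ifi27l2a (-4.87) and Lgals3bp (-3.87) fell too. Of 38 interferon-stimulated genes 33 fell, or 36 when adjusted over the list alone (median -2.24, adjusted p = 1.77e-04 with an estimated correlation). Cxcl10, the T cell attractant, fell by 5.30 (SE 0.19, adjusted p = 3.89e-09), as did Ccl12 (-4.44, adjusted p = 8.47e-08) and Ccl5 (-2.89), and 7 of 25 chemokines and cytokines fell, or 13 when adjusted over the list alone (median -0.44, adjusted p = 0.00392 with an estimated correlation). Among interferon-gamma-preferring genes, Iigp1 (-5.09), Gbp6 (-3.75), Irgm1 (-3.14) and Gbp7 (-2.37) fell, with 9 of 14 lower, or 11 when adjusted over the list alone (median -2.63, adjusted p = 0.00625 with an estimated correlation). Among 14 interferon signalling components, Ifnar1 fell by 1.31 (SE 0.17, adjusted p = 4.68e-04), as did Irf9 (-1.26, adjusted p = 3.10e-05) and the transcription factor gene Irf1 (-0.86, adjusted p = 0.0134), or 5 members when adjusted over the list alone (median -0.26, adjusted p = 0.00141 with an estimated correlation). The Irf1 call was lost without USP18ko replicate 1 (-0.84), USP18ko replicate 3 (-0.75) or double knockout replicate 1 (-0.83), 2 (-0.87) or 3 (-0.87).

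Class I and antigen processing, complement and activated microglia genes were lower in the double knockout as well. Psmb8 (-3.22), Psmb9 (-3.11) and H2-K1 (-2.16) fell, with 10 of 14 class I and antigen processing genes lower, or 11 when adjusted over the list alone (median -1.08, adjusted p = 5.88e-04 with an estimated correlation). C3ar1 fell by 2.04 (SE 0.15, adjusted p = 2.25e-06), as did C2 (-1.94) and Cfb (-1.42), with 8 of 12 complement genes lower, or 10 when adjusted over the list alone (median -1.40, adjusted p = 0.00199 with an estimated correlation). Cd52 (-3.30), Lyz2 (-2.04) and Tlr2 (-1.5) fell, with 5 of 18 activated microglia genes lower, or 10 when adjusted over the list alone (median -0.48, adjusted p = 5.88e-04 with an estimated correlation). Aif1 fell by 2.31 (SE 0.29, adjusted p = 3.60e-04) as did Laptm5 (-1.45) and Itgam (-0.72), with 3 of 13 microglia markers lower, or 7 when adjusted over the list alone (median -0.59, adjusted p = 0.0608 with an estimated correlation). The Itgam call was lost without USP18ko replicate 2 or 3 or any double knockout array (-0.75 to -0.57). It was also lost with quantile normalization, the Eif2s3y covariate and without both IFNARko replicate 1 and double knockout replicate 2. Ptprc (-2.46), Plac8 (-3.81), Ms4a7 (-2.06) and H2-Aa (-1.95) were the single members that fell in their lists. Their lists, the lymphocyte, monocyte and neutrophil, perivascular macrophage and class II genes, had medians of -0.13, -0.14, -0.40 and -0.70 and lost their calls with adjusted p = 0.238, 0.299, 0.0731 and 0.0745 with an estimated correlation. Of 23 reactive astrocyte genes 6 fell, Cxcl10, Gbp2, Psmb8 and Serping1 among them, or 8 when adjusted over the list alone (median -0.35, adjusted p = 0.00141 with an estimated correlation).

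Only 3 genes rose in the double knockout against USP18ko. Xist rose by 5.58 (SE 0.97, adjusted p = 0.00667), in step with the sex markers described above, and the average of its 3 probe sets lost the call (4.04). Kcne2, a potassium channel subunit gene of the choroid plexus that lies near Ifnar1, rose by 1.15 (SE 0.20, adjusted p = 0.00574). Its mean was 5.166 in USP18ko, against 6.004 in WT, 6.266 in IFNARko and 6.318 in the double knockout. The WT mean thus lay nearer to both groups without Ifnar1 than to USP18ko, and USP18ko was the group that stood apart. Tekt1, a gene of motile cilia, rose by 0.46 (SE 0.10, adjusted p = 0.0357). That call was lost without any of 7 single arrays (USP18ko replicates 1 to 3, double knockout replicates 2 and 3, WT replicate 3 and IFNARko replicate 2, range over all 12 arrays 0.42 to 0.53). The Tekt1 call was also lost with median centring (0.46), a trended and robust variance (0.46) and without both IFNARko replicate 1 and double knockout replicate 2 (0.42). In all, limma called 187 genes, 184 of them lower, each of these below the USP18ko arrays in all 3 double knockout arrays, with 614 at an unadjusted p under 0.05 and 2104 without overlap of the groups (16.98%, where chance gives 10%). With genes of low mean signal left out 37 genes were called, with array weights 500 (434 when estimated gene by gene), with these 2 groups alone 287, with the Eif2s3y level as a covariate 124 (H2-Aa at -1.92, Irf1 at -0.79 and Tekt1 at 0.55 then lost their calls), and without IFNARko replicate 1 and WT replicate 1 311. Camera called 14 of 27 lists lower and 4 higher, 8 held with an estimated correlation, all lower, and fry called 13. The choroid plexus and ependymal (median 0.25), mural cell (0.19), calcification (0.16) and meningeal fibroblast lists (0.14) were the 4 higher ones, with adjusted p = 0.111, 0.0731, 0.111 and 0.238 with an estimated correlation, and a list of endoplasmic reticulum stress genes was lower (median -0.10, adjusted p = 0.0745 with an estimated correlation).

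Loss of Usp18 where Ifnar1 was already absent was tested by the double knockout against IFNARko, groups that also differed in sex-linked transcripts. Ifit1 stood at 3.38 ± 0.26 in the double knockout and 3.38 ± 0.38 in IFNARko, and Cxcl10 at 3.62 ± 0.19 and 3.74 ± 0.16 (SD, n = 3 each), differences of 0.00 (SE 0.20) and -0.13 (SE 0.19). None of these levels is shown to be above background, so a difference in the underlying transcript may not have been detectable. The interferon-stimulated genes had a median log2 fold change of -0.02 (adjusted p = 0.932 by camera). Over the 142 genes higher in USP18ko, none of whose arrays enter this difference, the median was -0.08 and the range -0.90 to 0.70. Limma called 0 of 12393 genes, with 1022 at an unadjusted p under 0.05 and 2536 without overlap of the groups (20.5%, where chance gives 10%). The smallest p-values belonged to Xist (5.67, adjusted p = 0.228), Clec3b (1.28, adjusted p = 0.228), Matn4 (0.94, adjusted p = 0.228), 4921524J17Rik (-0.78, adjusted p = 0.228) and Ocel1 (1.54, adjusted p = 0.304), and Usp18 and Ifnar1 differed by 0.05 and 0.17. Camera called 0 of 27 lists, as did camera with an estimated correlation and fry. With array weights the fit called 814 genes, or 112 with weights estimated gene by gene, and the fit of these 2 groups alone called 2. Leaving out double knockout replicate 2 gave 3 genes and WT replicate 1 or 2 gave 1, while 2 lists were called without double knockout replicate 3 and 1 without any of WT replicates 1 and 3, USP18ko replicates 1 and 2, double knockout replicate 2 or IFNARko replicates 2 and 3.

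**Figure D4:**
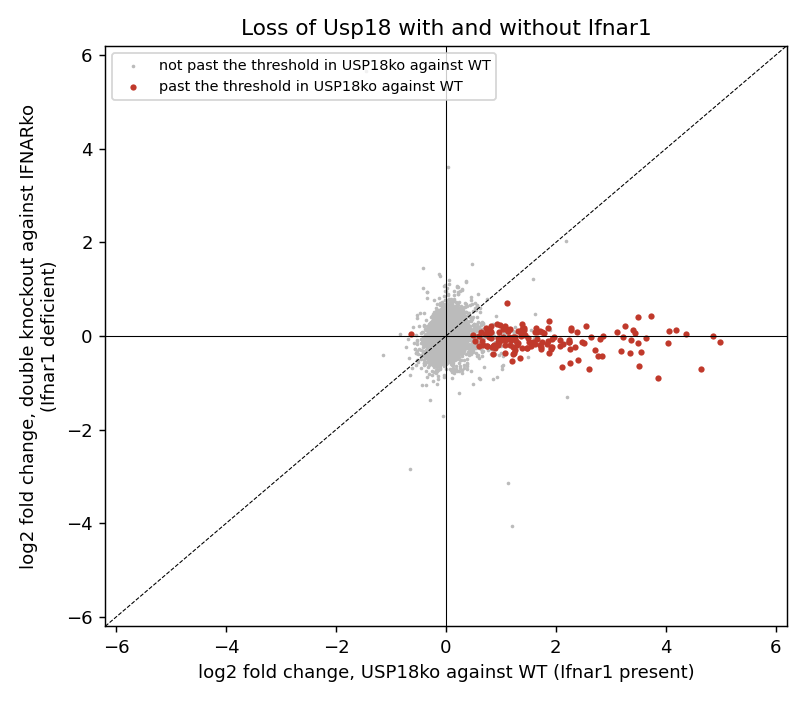
Each point is 1 of 12393 genes, with its log2 fold change in USP18ko against WT on the horizontal axis and in the double knockout against IFNARko on the vertical axis, and the dashed line marks equal values. The 142 genes past the threshold and higher in USP18ko (coloured, with Usp18 as the 1 that was lower) span 0.50 to 5.0 on the horizontal axis and -0.90 to 0.70 on the vertical axis.

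Whether the effect of Usp18 loss differed with and without Ifnar1 was tested by the interaction of both genotypes, that is, the double knockout minus IFNARko difference less the USP18ko minus WT difference. Interferon-stimulated genes had a smaller Usp18 effect without the receptor gene. The interaction was -4.87 for Ifit1 (SE 0.28, adjusted p = 1.01e-06), -5.12 for Cxcl10, -3.26 for Irf7 and -5.34 for Iigp1. Of 38 interferon-stimulated genes 28 passed, all lower, or 35 lower and 1 (Usp18) higher when adjusted over the list alone (median -2.16, adjusted p = 9.89e-04 with an estimated correlation). For class I and antigen processing genes 8 of 14 passed, or 11 when adjusted over the list alone (median -1.28, adjusted p = 0.00315 with an estimated correlation), among them Psmb8 (-2.85) and H2-K1 (-1.69). For interferon-gamma-preferring genes 8 of 14 passed, or 9 when adjusted over the list alone (median -2.77, adjusted p = 0.0243 with an estimated correlation), among them Gbp6 (-3.64) and Irgm1 (-3.19). These genes were high in IFNARko replicate 1, by a median of 0.84 over IFNARko replicates 2 and 3, which makes their interaction more negative. For complement genes 5 of 12 passed, or 10 when adjusted over the list alone (median -1.29, adjusted p = 0.0104 with an estimated correlation), among them C3ar1 (-1.70) and Cfb (-1.36). For chemokines and cytokines 5 of 25 passed, or 6 when adjusted over the list alone (median -0.36, adjusted p = 0.0283 with an estimated correlation), and for activated microglia genes 4 of 18, or 6 when adjusted over the list alone (median -0.45, adjusted p = 0.00948 with an estimated correlation), among them Cd52 (-3.03) and Tlr2 (-1.20). For reactive astrocyte genes 4 of 23 passed, or 5 when adjusted over the list alone (median -0.33, adjusted p = 0.00471 with an estimated correlation), and for perivascular macrophage markers 1 of 9, Ms4a7 (-1.97), or 5 when adjusted over the list alone (median -0.72, adjusted p = 0.0440 with an estimated correlation).

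Limma called 105 genes in the interaction, 102 lower and 3 higher, with 591 at an unadjusted p under 0.05. The 3 higher ones were Xist (7.13, SE 1.37, adjusted p = 0.0237), Clec3b (1.39, SE 0.28, adjusted p = 0.0368) and Matn4 (1.28, SE 0.23, adjusted p = 0.0156). Camera called 13 of 27 lists, all lower, and fry 9. The 8 lists above held with an estimated correlation, and the other 5 did not, namely interferon signalling components (median -0.14, adjusted p = 0.0803 with an estimated correlation), heat shock and RNA handling genes (-0.20, 0.0907), microglia markers (-0.40, 0.209), class II genes (-0.65, 0.329) and monocyte and neutrophil markers (-0.20, 0.508). The interactions of Usp18 (0.68, adjusted p = 0.116) and Ifnar1 (0.09) did not pass. With the Eif2s3y level of each array as a covariate 51 genes were called, and Irgm1 (-2.82), Cfb (-1.31), Clec3b (1.26), Matn4 (1.19) and Xist (3.56) lost their calls. The count was 20 with genes of low mean signal left out and 220 with gene-by-gene array weights. The Xist call was lost without any of 7 single arrays (USP18ko replicates 1 to 3, double knockout replicates 1 and 3, IFNARko replicates 2 and 3, values 6.94 to 7.28), that of Clec3b without any array but WT replicate 1, USP18ko replicate 3 and double knockout replicate 2 (1.21 to 1.45), and that of Matn4 without USP18ko replicate 3 (1.28) or double knockout replicate 1 (1.20) or 3 (1.26). The Xist call was also lost with the average of its probe sets (5.65), dim genes left out or a trended and robust variance (7.13 each) and without both IFNARko replicate 1 and double knockout replicate 2 (7.63), and that of Clec3b with each probe set by itself or dim genes left out (1.39 each) and quantile normalization (1.38).

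Knockout mice can carry DNA of another strain around the targeted gene, so the neighbours of both genes were examined, 50 measured genes on each side. Around Usp18, on chromosome 6, 3 of 100 neighbours were called in USP18ko against WT, namely Apobec1, C1ra and C3ar1, against 1.13% of the other genes (Fisher's exact test, two-sided, p = 0.107, adjusted p = 0.322 over 6 tests). Around Ifnar1, on chromosome 16, 5 of 100 were called in the double knockout against USP18ko, namely Cbr3, Il10rb, Kcne2 and the interferon-stimulated antiviral genes Mx1 and Mx2, against 1.47% of the other genes (Fisher's exact test, two-sided, p = 0.0173, adjusted p = 0.104). Of these, Kcne2 stood apart in USP18ko, and its WT mean lay nearer to both groups without Ifnar1. In the other 4 tests limma called 0 of 100 neighbours (Fisher's exact test on the called genes, adjusted p = 1 each). In IFNARko against WT and the double knockout against IFNARko 0 other genes were called either, so these tests could show no difference. In the double knockout against WT only 1 other gene was called. All 4 still count in the adjustment over 6 tests and are no evidence against an effect on neighbours. Neighbours at an unadjusted p under 0.05 were counted as well. Around Usp18 they were 11 of 100 in USP18ko against WT, against 4.54% of the other genes (Fisher's exact test, two-sided, p = 0.00607, adjusted p = 0.0225 over 6 tests), and 10 of 100 in the double knockout against WT, against 4.03% (exact p = 0.00751, adjusted p = 0.0225). With 20 genes on each side these shares were 20% and 17.5% (exact p = 3.93e-04 and 0.00104, adjusted p = 0.00236 and 0.00312). With 100 on each side they were 8% and 7%, which did not pass (exact p = 0.0264 and 0.0450, adjusted p = 0.135 each). Both comparisons use the same WT arrays, the counts pool genes that rose and genes that fell, and neighbouring genes are not independent. In the double knockout against IFNARko, which uses neither the WT nor the USP18ko arrays, 6 of 100 neighbours of Usp18 were at that p, against 8.27% of the other genes (exact p = 0.582, adjusted p = 0.698). Around Ifnar1 they were 7 or 8 of 100 in 3 comparisons (exact p = 0.129 to 0.734, adjusted p = 0.258 to 0.734).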

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

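The tests of degraded RNA, of a smaller neuron share, of a response to interferon-gamma, of mixed male and female RNA and of an extra X chromosome were chosen only after the results they bear on had been seen, and the count of other splits with an estimated correlation was chosen after the same count with the preset correlation had been seen. The other split counts and the test of admixed USP18ko RNA were set before their results were seen.

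The interaction test of limma called 105 genes, for which the USP18ko minus WT and the double knockout minus IFNARko differences were unlike. Not every call need be an effect of Usp18 loss. Sex-linked transcripts differed between these groups, and Xist is among the 105. Clec3b, another of them, stood at 6.59 in IFNARko and at 7.87 to 7.98 in the other groups. Camera called 13 gene lists in the interaction with its preset correlation and 8 with an estimated one. The interaction log2 values of the genes named under the rule were Iigp1 -5.34, Cxcl10 -5.12, Ifit1 -4.87, Gbp2 -4.76, Ifi27l2a -4.33, Ccl12 -4.18, Igtp -4.16, Ifit3 -4.06, Rsad2 -3.95, Rtp4 -3.89, Plac8 -3.71, Oasl2 -3.68, Gbp6 -3.64, Lgals3bp -3.38, Ifi202b -3.30, Irf7 -3.26, Irgm1 -3.19, Gbp2b -3.08, Cd52 -3.03, Ifih1 -2.91, Psmb9 -2.88, Psmb8 -2.85, Ptprc -2.77, Ccl5 -2.67 and Gbp7 -2.36. Smaller ones were Aif1 -2.17, Ms4a7 -1.97, Lyz2 -1.91, C3ar1 -1.70, H2-K1 -1.69, Tap1 -1.63, C2 -1.62, Laptm5 -1.61, Cfb -1.36, Ccl2 -1.31, Trim25 -1.23, Itgb2 -1.21, Tlr2 -1.20, Cybb -1.16, Serping1 -1.09, Irf9 -1.07 and Tap2 -0.86. The positive ones were Xist 7.13, Clec3b 1.39 and Matn4 1.28. Gbp2 and Iigp1 had SDs of 1.51 and 1.03 in IFNARko, and the Gbp2 interaction ran from -5.26 to -3.89 with single arrays left out, its call kept. Averaging the probe sets of a gene ended the calls of Tap1 (-0.41, 1 of its probe sets having the opposite sign), Trim25 (-0.82) and Xist (5.65). Among the named genes that are kept when dim genes are left out, the calls of Laptm5 (-1.61), Lyz2 (-1.91), Trim25 (-1.23), Xist (7.13) and Clec3b (1.39) were lost. Named genes removed with the dim ones have no value there. Calls were also lost for Trim25 with each probe set by itself (-1.23) or median centring (-1.22), for Clec3b with each probe set by itself (1.39) or quantile normalization (1.38), and for Xist with a trended and robust variance (7.13). Without both IFNARko replicate 1 and double knockout replicate 2, Aif1 (-2.02), Lyz2 (-1.60), C2 (-1.55), Laptm5 (-1.52), Trim25 (-1.27) and Xist (7.63) lost their calls, as did Trim25 without both IFNARko replicate 1 and WT replicate 1 (-1.29). With the Eif2s3y level of each array as a covariate, a setting chosen after seeing the data, 16 of these genes lost their calls. The values of Aif1 (-1.31), Laptm5 (-0.99) and Xist (3.56) moved by over 1.5 times, and the others were Gbp2 (-4.62), Irgm1 (-2.82), Tap1 (-1.70), Lyz2 (-1.65), C2 (-1.59), Trim25 (-1.34), Cfb (-1.31), Ccl2 (-1.17), Itgb2 (-1.11), Irf9 (-1.08), Serping1 (-0.91), Clec3b (1.26) and Matn4 (1.19). Calls of 8 of the named genes were lost without single arrays. They were Aif1 (USP18ko replicates 2 and 3, IFNARko replicate 1 and each double knockout array, values -2.19 to -1.99), Laptm5 (USP18ko replicates 2 and 3 and each double knockout array, -1.64 to -1.47), Lyz2 (WT replicates 1 and 3, USP18ko replicates 1 and 3, double knockout replicates 1 and 2, -1.91 to -1.73), Trim25 (all arrays but WT replicate 1, USP18ko replicate 2 and IFNARko replicate 2, -1.31 to -1.06), Tap2 (WT replicate 3, USP18ko replicates 1 and 3, double knockout replicates 1 and 2, IFNARko replicates 2 and 3, -0.87 to -0.77), Xist (USP18ko replicates 1 to 3, double knockout replicates 1 and 3, IFNARko replicates 2 and 3, 6.94 to 7.28), Clec3b (all arrays but WT replicate 1, USP18ko replicate 3 and double knockout replicate 2, 1.21 to 1.45) and Matn4 (USP18ko replicate 3, double knockout replicates 1 and 3, 1.20 to 1.28).

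Other splits of the 12 arrays into groups of the same sizes were refitted, 100 in all with the real one. For the 105 genes of the interaction the real split alone reached that count (1 of 100), and the highest other count was 1. For the 13 lists called with the preset correlation, 19 of 100 splits reached that count and the highest other was 16, so chance was not excluded. For the 8 lists called with an estimated correlation it was 1 of 100 (highest other 1). Shuffling all labels also breaks up the difference of USP18ko from the other groups, which widens the spread of those genes. The counts of 1 of 100 thus set the genotypes against no grouping at all. They do not test main effects without an interaction, so chance is not excluded for the interaction itself. The 10 splits of 2 groups of 3 arrays are too few for a share under 0.05. The real gene counts and the highest others were 143 and 0 in USP18ko against WT, 1 and 3 in IFNARko against WT, 2 and 3 in the double knockout against WT, 187 and 0 in the double knockout against USP18ko, and 0 and 0 in the double knockout against IFNARko. For lists called with the preset correlation the same pairs were 13 and 15 (5 of 10 splits reached the real count), 3 and 7 (9 of 10), 4 and 7 (9 of 10), 18 and 15 (1 of 10), and 0 and 6 (10 of 10).

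IFNARko replicate 1 stood apart, with a beta-actin 3' minus 5' difference of 1.48 (0.20 to 0.54 in the others), a Gapdh difference of 0.47 (-0.37 to -0.17 in the others) and the lowest correlations with other arrays. Degraded or poorly labelled RNA is a candidate explanation, and the beta-actin value lies outside the range of the other 11 arrays. A smaller share of neurons in the piece of tissue is argued against as the whole cause. The neuron list was lower by a median of -0.61 than in IFNARko replicates 2 and 3 (random lists -0.22 to 0.23), but oligodendrocyte genes, which should then be higher, were also lower (-0.26). Oligodendrocyte precursor markers were lower as well (-0.38, random lists -0.36 to 0.42). Meningeal fibroblast markers lay near the top of their random range (0.36, random lists -0.31 to 0.36). Other differences in the composition of the tissue were not tested, and a biological difference of that sample stays open.

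Interferon-gamma-preferring genes, among them GTPase genes with close paralogs that may share signal, were high in the same array, with a median 0.84 above IFNARko replicates 2 and 3. The list lay at percentile 100 of 10000 random lists of matched level in that array, so a rise shared by genes of that level does not account for it. The random lists were not matched on where probes lie along the transcript, and paralogs are not independent. Degraded RNA as the cause therefore stays open. Admixed USP18ko RNA is argued against, since interferon-stimulated genes would need a median share of 5.30% (quartiles 0.76 to 10.8) and interferon-gamma-preferring genes 19.6% (16.3 to 23.6). A response to interferon-gamma in that animal may be the cause and stays open, since class II genes outside that list lay at percentile 63.7. Monocyte and neutrophil markers were also above the random range in that array (median 0.47, percentile 98.5, random lists 0.08 to 0.45), and whether such cells account for the pattern was not tested.

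Xist and Y-linked transcripts appeared together in double knockout replicate 2. Male and female RNA mixed in 1 sample would give shares of the male and female levels that sum to 1, and the sum was 1.15, with a range of 0.776 to 2.05 over the reference arrays. An animal with an extra X chromosome would give a sum of 2, and the highest sum was 2.05, so these sums leave both open. They use 1 of 3 Xist probe sets. On the others, double knockout replicate 2 read 8.08 and 4.47. The other arrays with high Xist read more, 8.47 to 9.84 and 5.33 to 6.55, so the sum of 2.05 rests on the probe set used. Sums with the other probe sets were not computed, and the explanations are not told apart here. No biological explanation from the genotypes was tested.

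Outside the gene tests, 33 of 2246 probe sets with several genes or no name passed in USP18ko against WT, 32 higher and 1 lower, 24 of them with several genes. In the same fit 3 passed in IFNARko against WT (2 higher, 1 lower), 33 in the double knockout against USP18ko (1 higher, 32 lower), 25 in the interaction (1 higher, 24 lower) and 0 in the double knockout against WT or IFNARko, where 100 and 156 were at an unadjusted p under 0.05 by limma.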

How the results depend on the processing

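The Eif2s3y covariate, gene-by-gene array weights and the fits without 2 arrays were chosen after seeing the data. Of the 44 named calls in USP18ko against WT, 44 in the double knockout against USP18ko and 45 in the interaction, Usp18 and Ifnar1 not counted, 1091 of 1110, 1076 of 1111 and 1003 of 1093 values under other settings stayed past the threshold, and 0 reversed in sign. In the double knockout against WT, Pnpla3, the 1 such call, was lost in 14 of 25 values, namely for each probe set by itself (-1.49), quantile normalization (-1.48), the replicate block (-1.49), the Eif2s3y covariate (-1.43) and 10 single arrays (-1.54 to -1.43). No detection calls were used here, so which signals lie above background stays open. Leaving out dim genes keeps 7436 genes and removes 108 of the 143 called in USP18ko against WT, 143 of 187 in the double knockout against USP18ko and 74 of 105 in the interaction. Named genes removed in this way have no value under that setting and are not counted in the totals above. The default array weights stopped before converging, and both methods differ for WT replicate 3 (0.22 and 3.69). Eif2s3y was low in double knockout replicates 1 and 3 and WT replicate 1, and its covariate moved interaction values as well as calls, Aif1 from -2.17 to -1.31, Laptm5 from -1.61 to -0.99 and Xist from 7.13 to 3.56. A fold threshold of 1 ends calls of smaller values by construction. Fewer arrays or genes enter some fits. Otherwise the cause was not tested. A covariate of Ddx3y was not run, since no probe set of that gene alone was used here, and a floor was not applied because the values were already logs.

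Gene counts are given in the order USP18ko against WT (143), IFNARko against WT (1), double knockout against WT (2), double knockout against USP18ko (187), double knockout against IFNARko (0) and interaction (105). Leaving out dim genes gave 28, 1, 0, 37, 0 and 20. Array weights gave 2 in IFNARko against WT, 500 in the double knockout against USP18ko and 814 against IFNARko, and gene-by-gene weights 345, 1264, 843, 434, 112 and 220. Each probe set by itself gave 3 in IFNARko and 0 in the double knockout against WT, where quantile normalization also gave 0. The 2 groups alone gave 0 in IFNARko against WT, and 287 and 2 in the double knockout against USP18ko and IFNARko. The Eif2s3y covariate gave 1 in the double knockout against WT, 124 against USP18ko and 51 in the interaction. For IFNARko against WT and the double knockout against WT, USP18ko and IFNARko, leaving out IFNARko replicate 1 and WT replicate 1 gave 11, 58, 311 and 1, and leaving out IFNARko replicate 1 and double knockout replicate 2 gave 3 and 1 against WT and 1 against IFNARko. Leaving out 1 array gave 117 to 184, 0 to 5, 0 to 3, 139 to 239, 0 to 3 and 83 to 115.

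List counts in the same order were 13, 3, 4, 18, 0 and 13. Leaving out dim genes gave 7, 1, 2, 9, 0 and 5, an estimated correlation 8, 0, 0, 8, 0 and 8, and fry 0 in IFNARko and in the double knockout against WT. In IFNARko against WT, array weights gave 10, gene-by-gene weights 12, the Eif2s3y covariate 9, and leaving out IFNARko replicate 1 gave 11 with double knockout replicate 2 and 12 with WT replicate 1. In the double knockout against WT, gene-by-gene weights gave 7, as did leaving out IFNARko replicate 1 and WT replicate 1. In the double knockout against IFNARko, the average of probe sets gave 2, median centring, either array weights and the Eif2s3y covariate 1, and leaving out IFNARko replicate 1 and double knockout replicate 2 gave 2. Leaving out 1 array gave 13 to 16, 1 to 11, 3 to 6, 15 to 19, 0 to 2 and 11 to 18.

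Ifnar1 in IFNARko against WT lost its call under the 2 groups alone (-1.40) and without IFNARko replicate 1 and double knockout replicate 2 (-1.30), with single arrays left out at -1.60 to -1.21. In the double knockout against WT it lost its call for each probe set by itself, dim genes left out and the 2 groups alone (-1.23 each), quantile normalization (-1.24) and without IFNARko replicate 1 and double knockout replicate 2 (-1.21), with single arrays left out at -1.43 to -1.04. Against USP18ko it kept its call at -1.39 to -1.26. Usp18 in USP18ko against WT lost its call under array weights (-0.66), a fold threshold (-0.63) and the 2 groups alone (-0.63), with single arrays left out at -0.74 to -0.57, and is itself removed with the dim genes. In the double knockout against WT it passed under gene-by-gene weights (-0.49), with single arrays left out at -0.73 to -0.56. Around Ifnar1 in the double knockout against USP18ko, a width of 100 genes on each side, or 151 neighbours in all, gave 5 called neighbours (Fisher's exact test, two-sided, p = 0.0772, adjusted p = 0.463 over 6 tests), and 20 on each side gave 3 of 40 (exact p = 0.0219, adjusted p = 0.131), against 5 of 100 with 50 on each side (exact p = 0.0173, adjusted p = 0.104).

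Replicate numbers showed no clear pairing of the arrays. Deviations of arrays with the same number correlated by 0.03 on average (range -0.15 to 0.27, with 6 of 18 pairs over 0.1). For arrays with other numbers the average was -0.02, with 7 of 36 pairs over 0.1. Of 12 arrays, 5 correlated best with their own number. A batch shared by arrays of the same number is not excluded. With the replicate block, gene counts were 142, 0, 0, 178, 0 and 102 and list counts 13, 4, 4, 18, 0 and 14, and Ifnar1 kept its values (-1.40 in IFNARko and -1.23 in the double knockout against WT) without its calls. The block also ended the calls of Pnpla3 in the double knockout against WT (-1.49), Tekt1 in the double knockout against USP18ko (0.46) and Clec3b in the interaction (1.39), and no other named call. The cause was not tested.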

Other observations

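The genes in this part were picked after their values were seen, and the comparisons are those of the report, with no further tests. Of the 142 genes higher in USP18ko than in WT, 68 belonged to none of the preset lists. Of these 68, 65 fell in the double knockout against USP18ko, which shares the USP18ko arrays they were picked on, and 38 passed in the interaction. The 3 that did not pass against USP18ko were Cyba (-1.11), Clec2d (-0.77) and Avp (-0.40). The 10 with the largest log2 fold changes among them were Ifi202b (3.73), Gbp2b (3.50), AW112010 (3.22), Ifi47 (2.84), Fcgr1 (2.72), Lgals9 (2.55), Ms4a6d (2.51), Ms4a6b (2.26), Ms4a6c (2.13) and Mpeg1 (1.93). Fcgr1 and Fcgr4, receptors for the constant part of immunoglobulin G, rose by 2.72 (SE 0.20, adjusted p = 3.88e-06) and 1.84 (SE 0.22), and Fcer1g, the signalling chain they share, by 1.43. The lysosomal protease genes Ctss and Ctsc rose by 1.91 (SE 0.24, adjusted p = 5.82e-04) and 1.48. Mpeg1, Spi1 and Irf8, a pore-forming protein and 2 transcription factors of myeloid cells, rose by 1.93, 0.75 and 0.96. Adjusted p-values are from limma, and each gene was higher in all 3 USP18ko arrays than in all 3 WT arrays.

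Tspo, a mitochondrial membrane protein whose ligands are used to image glial activation, rose by 1.43 (SE 0.20, adjusted p = 0.00108). Cd274, which encodes the inhibitory ligand PD-L1, rose by 1.07, Lgals9, an immune-regulating lectin gene, by 2.55, and Il18bp, an inhibitor of interleukin-18, by 1.39. Icam1, an adhesion molecule of endothelium and leukocytes, rose by 1.34, and the lipid-binding apolipoprotein gene Apod by 1.56 (SE 0.25, adjusted p = 0.00386). Tlr3, a receptor of double-stranded RNA, rose by 1.63 (SE 0.11). Avp, the vasopressin gene of hypothalamic neurons, rose by 1.11 (adjusted p = 0.0406) and differed by -0.40 in the double knockout against USP18ko (adjusted p = 1.00).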
